A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

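Per the labels, cells were taken from a fermenter, fixed with formaldehyde, treated with an enzyme that removes the cell wall, and their nuclei were treated with transposase before library preparation. The deposited table gives raw counts per peak for 1 common list of 2086 peaks in 18 libraries, with chromosome, start and end. Per the submitters' processing notes, Trimmomatic, Bowtie2 and MACS2 were used with genome build R64; versions, the counting tool, any shift of insertion sites, the handling of duplicate and multiply mapping reads, and whether peaks were called on pooled libraries are not given in the sources used here. Duplicates kept in the counts would make counts less independent than they look, and multiply mapping reads bear on the ribosomal DNA, subtelomeric PAU and COS families and paralogous ribosomal protein and histone genes, whose peaks are uncertain where copies are near-identical. Counting intervals and floors therefore cover counting error only. All 18 count columns were matched to samples by the column name given in the sample description, and 0 columns were left unmatched.

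Groups were the labelled phases. The series was collected in 2 batches, but the labels used here do not assign libraries to them, so batch could not be a covariate. Time points are an order with no minutes. Peak starts were written 1-based. A peak was linked to each coding gene whose annotated 5' end (the start of the coding gene model, with strand from the systematic name) lay within 500 bp, which linked 2664 genes; 691 nuclear peaks were linked to genes on both strands, and such a peak cannot say which of its genes it serves. Where several peaks linked to a gene, the one with the highest mean CPM stood for it.

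Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, filterByExpr, TMM scaling, robust dispersion) in R 4.3.3, with Benjamini-Hochberg adjustment over peaks and a threshold of 0.05; filterByExpr removed 0 peaks. All 18 libraries entered the phase fits, in which the phases shared the dispersion estimate of each peak. The comparison of early and late Reductive Charging used its 8 libraries and tested 2085 peaks. The time course used a natural spline with 4 degrees of freedom. Standard errors were taken from the fold change and its F value. Gene lists were tested with camera (limma 3.58.1; preset correlation 0.01) on log2 CPM with a prior count of 2, with an estimated correlation and fry beside it; 18 of 19 lists had at least 5 linked peaks, and the list of 3 cycle marks (RPL17B, MRPL10, POX1) had 2. A list score was the mean log2 CPM of a list's peaks minus that of all nuclear peaks, tested by two-sided exact permutation of libraries. Exact permutation tests take libraries as freely exchangeable, which neighbouring time points are not. The lists, the designs, the rule for named genes and the alternative settings listed last were fixed before the data were examined.

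The rule named, per comparison, the 5 largest and 5 most negative log2 fold changes among peaks past the threshold that link to a gene with a standard name outside the PAU, COS, transposon, transfer RNA and ribosomal DNA families; the 3 list members with the smallest p in the comparison where the list's camera p was smallest; and the 3 cycle marks throughout. Since no peak passed in the phase comparisons with all 18 libraries, the first part was also applied to a fit of the 13 libraries with at most 10% of nuclear peaks at 0. That fit (6 Reductive Charging, 5 Oxidative and 2 Reductive Building libraries), the score tests, a fit without the 2 libraries with more than 50% of nuclear peaks at 0, nuclear peaks only, and limma-voom with library quality weights were chosen after seeing the data. The alternatives fixed beforehand were DESeq2 size factors, total-count scaling, loess offsets, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, a linear time covariate, subsets of Reductive Charging, only the compared groups, trimmed phases, other spline degrees of freedom, other linking distances and leaving out each library.

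The tests were checked on 3 simulated tables per setting, with 200 of 2086 peaks changed between Oxidative and Reductive Charging. With all 18 libraries edgeR recovered 2.99%, 25.9% and 60.6% of peaks changed 2-fold, 4-fold and 8-fold, and with the 13 libraries 42.3%, 78.6% and 94.9%. Plots were drawn with matplotlib 3.10.9.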

Results

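Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in budding yeast grown in a fermenter and sampled at 18 ordered time points of the yeast metabolic cycle. The cycle alternates between a respiratory phase and reductive phases, and the labels put 8 libraries in Reductive Charging (time points 1 to 5 and 16 to 18), 5 in Oxidative (6 to 10) and 5 in Reductive Building (11 to 15). No time point had a second library, so the libraries of a phase stood as its replicates. The p-values therefore measure only the spread between time points within phases. The table held 2086 peaks, of which 2042 were nuclear peaks outside the ribosomal DNA, 32 lay on the mitochondrial genome and 12 in the ribosomal DNA. Of the nuclear peaks, 1766 (86.5%) lay within 500 bp of the 5' end of a coding gene, against a mean of 61.5% when the peaks were shifted along their chromosomes. The median peak was 599 bp long.

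Total counts per library ran from 21254 (time point 16) to 29314373 (time point 4). Coverage of the nuclear peaks was uneven: 229, 498, 1336, 1720 and 266 of the 2042 had 0 counts at time points 11, 13, 15, 16 and 18, against at most 42 in each of the other 13 libraries, called well-covered here. A count of 0 at time point 16 still allows a share of up to 0.0141% of that library's counts (3 counts of the total), against 1.02e-05% at time point 4. The 5 poorly covered libraries comprised 3 of the 5 Reductive Building and 2 of the 8 Reductive Charging libraries. Across nuclear peaks, the median Spearman correlation between libraries was 0.937 within time points 1 to 7 and 0.726 within time points 8 to 18, or 0.823 among the well-covered libraries after time point 7. Peaks are not independent replicates.

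**Figure D1:**
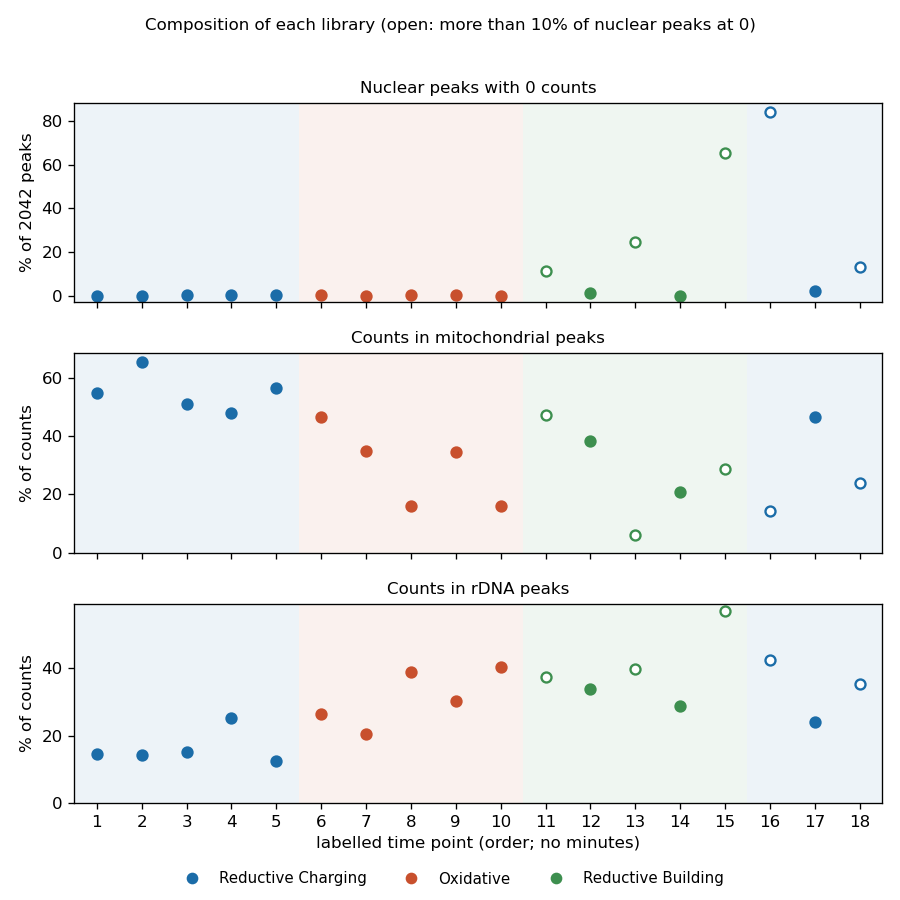
Share of the 2042 nuclear peaks with 0 counts (top), share of counts in mitochondrial peaks (middle) and in ribosomal DNA peaks (bottom), in percent, by labelled time point; each point is 1 library, coloured by phase, and open points are the 5 libraries with more than 10% of nuclear peaks at 0. Time point 16 reaches 84.2% of peaks at 0, and the mitochondrial share is highest at time point 2, at 65.5%.

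Mitochondrial DNA gave a large part of the counts. Its peaks held 45.1% ± 17.3 (SD, n = 8) of counts in Reductive Charging, 29.6% ± 13.4 (n = 5) in Oxidative and 28.3% ± 15.9 (n = 5) in Reductive Building libraries. The Oxidative mean minus that of Reductive Charging was -15.5 percentage points, within the spread between libraries (two-sided exact permutation test, p = 0.121; adjusted p = 0.242 over 16 tests of composition). Without time point 16 it was -19.9 points (exact p = 0.0328). In the 13 well-covered libraries, a set chosen after seeing the data, the difference was -24.2 points (29.6% against 53.8%, exact p = 0.00216, adjusted p = 0.0260 over 12 tests). Of the 6 Reductive Charging libraries in that set 5 were early ones. Within Reductive Charging the share was 55.2% ± 6.63 (n = 5) early and 28.3% ± 16.7 (n = 3) late. The difference was 27.0 points (exact permutation p = 0.0179, the smallest possible, adjusted p = 0.132). The late shares were 14.1%, 46.7% and 24.0% at time points 16, 17 and 18. Time point 17, the only well-covered late library, lay just below the lowest early share (48.1% at time point 4). Ribosomal DNA peaks, from the repeats that encode ribosomal RNA, held 22.9% ± 11.1 (n = 8), 31.3% ± 8.39 (n = 5) and 39.4% ± 10.6 (n = 5) in the same order. Reductive Charging minus Reductive Building was -16.5 points (exact p = 0.0264, adjusted p = 0.132). The Wilson 95% interval of the mitochondrial share was 13.7% to 14.6% at time point 16 and 48.0% to 48.1% at time point 4, for counting error only.

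The Oxidative phase was compared with Reductive Charging to ask which promoters differ in accessibility between respiration and Reductive Charging. Promoter peaks of stress genes and chaperones, of trehalose and glycogen metabolism, and of the glyoxylate cycle, gluconeogenesis and acetyl-CoA supply were less accessible in Oxidative than in Reductive Charging libraries, relative to all peaks. The stress list held 32 peaks, including the catalase gene CTT1 and the small heat-shock protein gene HSP26. It scored -0.49 ± 0.42 (log2, SD, n = 5) in Oxidative and 0.49 ± 0.32 (n = 8) in Reductive Charging libraries, a difference of -0.99. The trehalose and glycogen list (16 peaks, storage carbohydrates) differed by -1.25 (-0.56 ± 0.48 against 0.69 ± 0.54), and the glyoxylate list (20 peaks, use of 2-carbon substrates) by -0.80 (-0.46 ± 0.29 against 0.34 ± 0.35). For the stress and glyoxylate lists all 5 Oxidative libraries scored below all 8 Reductive Charging libraries. That gives the smallest exact permutation p possible (two-sided, p = 0.000777, adjusted p = 0.0210 over 54 pairs of list and comparison). For trehalose and glycogen the exact p was 0.00233 (adjusted p = 0.0420). Sulfur assimilation and methionine promoters scored higher in Oxidative libraries, 0.15 ± 0.17 (n = 5) against -0.09 ± 0.07 (n = 8; exact p = 0.00311, adjusted p = 0.0420). These score tests were added after seeing the data. They take libraries as freely exchangeable, but the Oxidative libraries were neighbouring time points (6 to 10), which are not independent. Their exact p may therefore be too small. In the 13 well-covered libraries the differences were -0.88 for stress, -0.995 for trehalose and glycogen and -0.72 for glyoxylate, and none passed the adjustment (exact p = 0.00216, 0.00433 and 0.00216, adjusted p = 0.0584 each). Stress and glyoxylate were again fully separated, at the smallest exact p that 5 against 6 libraries can give (0.00216). Sulfur differed by 0.21 (exact permutation, adjusted p = 0.140).

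By the planned list test, camera with a preset correlation of 0.01, these were 3 of 54 pairs past the threshold, with adjusted p = 7.19e-07 for trehalose and glycogen, 5.97e-06 for stress and 0.000882 for glyoxylate. With an estimated correlation none was called (adjusted p = 0.980 for each). By fry, which asks whether a list moves on balance one way and does not compare it with other peaks, 0 of the 54 passed (lowest adjusted p = 0.716). In the 13 well-covered libraries camera called 12 of 54 pairs and fry 9 (lowest adjusted p = 0.00161), and with an estimated correlation 0 were called (lowest adjusted p = 0.0513). Of the members, 28 of 32 stress peaks, 15 of 16 trehalose and glycogen peaks and 18 of 20 glyoxylate peaks lay below the median of all peaks. Of these members 0 passed the edgeR test singly over all peaks, and 0 adjusted over the list alone. HSP26 had a log2 fold change of -2.08 ± 0.90 (SE), and CTT1 had -1.26 ± 0.64. TSL1, a subunit of the trehalose synthase complex, had -0.93 ± 0.39, TPS1, its synthase subunit, -0.79 ± 0.40, and the acetaldehyde dehydrogenase gene ALD6 -0.99 ± 0.41 (edgeR, adjusted p = 1.00 for each). The median log2 fold change of all peaks on the scale of the list test was 1.20. The counts of members below the median refer to that value, so such a member could have a fold change above 0. Camera itself compared the test statistics of a list's peaks with those of the other peaks.

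**Figure D2:**
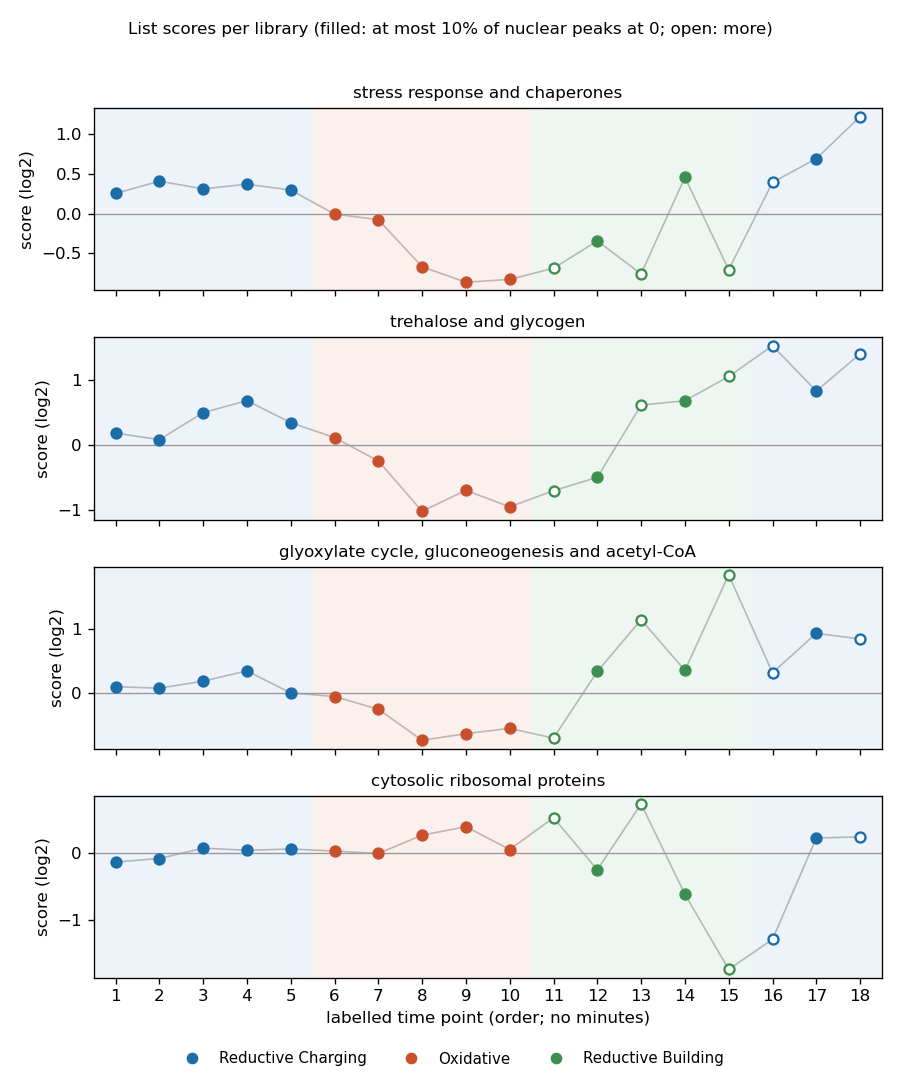
List score by labelled time point for 4 gene lists: mean log2 CPM of the list's peaks minus the mean over all nuclear peaks, centred on the 13 well-covered libraries; each point is 1 library, coloured by phase, and open points are libraries with more than 10% of nuclear peaks at 0. The stress score is between 0.25 and 0.41 at time points 1 to 5, between -0.87 and -0.67 at 8 to 10, and 1.22 at time point 18; the ribosomal protein score is -0.25 and -0.62 at the well-covered Reductive Building time points 12 and 14.

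No single peak passed in this comparison (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 2086; 52 at an unadjusted p under 0.05, against 104.3 expected by chance; 0 with DESeq2 and 0 with limma-voom). With library quality weights, chosen after seeing the data, limma-voom called 100, of which 47 were higher and 53 lower. In the 13 well-covered libraries 58 peaks passed, 31 higher and 27 lower in Oxidative. The highest was the promoter shared by SHM2, a serine hydroxymethyltransferase, and REX2 (chromosome XII, 259391 to 260352, build R64), with a log2 fold change of 2.71 ± 0.44 (SE; edgeR adjusted p = 0.0109). Next came the peak of the lysine biosynthesis gene LYS12 and the mitochondrial ribosomal protein gene RSM25 (2.03 ± 0.45), the ribosomal protein gene RPS14B (2.02 ± 0.48), SBP1, an RNA-binding protein (1.91 ± 0.45), and the shared peak of the pheromone receptor gene STE2 and GYP8 (1.75 ± 0.38), each with edgeR adjusted p = 0.0426. Lowest was the promoter of UGP1, which makes UDP-glucose for glycogen and trehalose, shared with AIM26 (-1.67 ± 0.43, adjusted p = 0.0451). Then came that of PAI3 and SIP18 (-1.59 ± 0.36), CYB2, a lactate dehydrogenase (-1.45 ± 0.30, adjusted p = 0.0343), CCP1, cytochrome c peroxidase, shared with GPT2 (-1.37 ± 0.33) and the acetate transporter gene ADY2 (-1.33 ± 0.29). By camera the same 3 lists were lower in this set (adjusted p = 1.19e-08 for stress, 2.24e-06 for trehalose and glycogen and 3.83e-07 for glyoxylate; adjusted p = 0.191, 0.239 and 0.193 with an estimated correlation). Of the stress peaks 5 fell (10 adjusted over the list alone): CTT1, by 1.02 on the log2 scale (SE 0.26, edgeR adjusted p = 0.0446), and those of HSP12, XBP1, PAI3 (shared with SIP18) and DDR2. Trehalose and glycogen had 2 that fell, TPS2 and UGP1 (8 adjusted over the list alone), and glyoxylate had 1, ADY2 (7 adjusted over the list alone). Where such members fall outside the rule, here and below, they were picked after their values were seen.

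The same set had 3 lists higher in Oxidative libraries by camera: histones (6 peaks, adjusted p = 0.000799), cytosolic ribosomal proteins (120 peaks, adjusted p = 0.00174) and sulfur assimilation and methionine (26 peaks, adjusted p = 0.0129). With an estimated correlation their adjusted p were 0.191, 0.446 and 0.191, and fry did not call the ribosomal proteins (adjusted p = 0.0980). Histone peaks that rose were 3 (4 adjusted over the list alone), those of HTA2 with HTB2, of HHT2 with HHF2, and of HTZ1. The divergent promoter of HTA2 and HTB2 rose by 0.67 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0426), and that of HTA1 and HTB1 had 0.73 ± 0.22 (adjusted p = 0.0817). Ribosomal protein peaks that rose were 3, those of RPS14B, RPL18B (shared with TOS6) and RPL21B (3 adjusted over the list alone). Sulfur peaks that rose were 2, of MET6 and MUP1 (2 adjusted over the list alone). The 58 calls depended on single libraries: 5, 5, 9, 7 and 12 were left without time point 1, 2, 3, 4 and 5, and 6, 5 and 4 without 8, 9 and 10, against 119 without time point 6. With total-count scaling, which put the median of all peaks at 0.52 against 0.02, the count was 114, of which 104 were higher.

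Reductive Building was compared with Oxidative to ask which promoters change as respiration ends. In the 2 well-covered Reductive Building libraries against the 5 Oxidative ones, the ribosomal protein list was lower relative to all peaks by camera (adjusted p = 9.60e-19; adjusted p = 0.0513 with an estimated correlation). Its score differed by -0.58, with an exact permutation p of 0.0476, the smallest 2 against 5 can give, and did not pass the adjustment (adjusted p = 0.161). In all 18 libraries the score differed by -0.42 (exact permutation p = 0.437, adjusted p = 0.693). Of 120 ribosomal protein peaks, 105 lay below the median of all peaks, 12 fell and 0 rose (41 fell and 1 rose when adjusted over the list alone). The lowest were RPL9A (-2.08 ± 0.34, SE), RPS24B (-1.85 ± 0.29), the peak of RPL17B and ATG27 (-1.52 ± 0.25), each with edgeR adjusted p = 0.00482, and RPS4B with MNL1 (-1.48 ± 0.29, adjusted p = 0.0160). DSE4, a daughter-cell glucanase gene, had -2.02 ± 0.49 (adjusted p = 0.0459). Highest were GLC3, the glycogen branching enzyme (1.92 ± 0.38, adjusted p = 0.0165), BAT2 with HMS2 (1.66 ± 0.36), ATO2, an ammonia exporter (1.66 ± 0.36), GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase (1.55 ± 0.29, adjusted p = 0.0146), and CIT1, mitochondrial citrate synthase (1.39 ± 0.31, adjusted p = 0.0288). The peak of POX1 had 1.54 ± 0.49 and did not pass.

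By camera in the 13 libraries, glyoxylate (adjusted p = 6.13e-06), stress (0.00163) and trehalose and glycogen (0.00758) were higher, with adjusted p of 0.239, 0.446 and 0.473 with an estimated correlation. At time points 12 and 14, stress scored -0.35 and 0.46, and trehalose and glycogen -0.50 and 0.68. Both scores at 12 lay in the Oxidative range. In all 18 libraries the score differences were 1.05 for glyoxylate, 0.08 for stress and 0.79 for trehalose and glycogen (exact permutation adjusted p = 0.273, 0.882 and 0.303). Glyoxylate peaks that rose were 3, of ACH1, CIT2 and CIT1 (8 adjusted over the list alone). Stress had 1, of HSP12 (2 adjusted over the list alone), and trehalose and glycogen 1, of GLC3 (5 adjusted over the list alone). In all 18 libraries no peak passed (edgeR, 0 of 2086; 101 at an unadjusted p under 0.05; 13 with DESeq2, 3 with limma-voom). No list passed either: ribosome biogenesis, of which 23 of 31 peaks lay below the median of all peaks, and glyoxylate, of which 6 of 20 did, both had adjusted p = 0.0517. Adjusted over the list alone, 1 glyoxylate peak (ACH1) and 1 stress peak (SIP18 with PAI3) rose. Ribosome biogenesis scored lower in all 5 Reductive Building than in all 5 Oxidative libraries (-0.79 ± 0.61 against 0.19 ± 0.21; exact permutation p = 0.00794, the smallest possible; adjusted p = 0.0714). The poorly covered time points 11, 13 and 15 scored -1.14, -1.44 and -1.10, and in the 13 well-covered libraries the difference was -0.32 (-0.13 against 0.19; exact permutation p = 0.0952, adjusted p = 0.250). RPL17B had -0.91 ± 0.77 and POX1 0.76 ± 1.10. The poorly covered time points 11 and 13 had ribosomal protein scores of 0.53 and 0.73, above every Oxidative library, and time point 15 had -1.75. The 31 calls of the 13-library comparison were 0 with total-count scaling, and 60, 15, 16, 14, 104 and 94 without time point 7, 8, 9, 12, 14 and 17. Without time point 14, 16 of the 31 were among the 104, and time point 12 was then assumed to vary like the other groups.

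Reductive Charging was set against Reductive Building to compare the reductive phases. In the 13 well-covered libraries the ribosomal protein list was higher in Reductive Charging (camera adjusted p = 1.19e-11; adjusted p = 0.132 with an estimated correlation; score difference 0.46, exact permutation p = 0.0357, adjusted p = 0.161). In all 18 libraries the score difference was 0.16 (exact permutation p = 0.702, adjusted p = 0.880). Of its 120 peaks 10 were higher and 1 lower past the threshold (22 and 1 adjusted over the list alone). RPL9A was higher by 1.41 ± 0.32 (log2, SE), RPL23B by 1.36 ± 0.24, RPL33B by 1.25 ± 0.20 and the peak of RPL17B by 1.14 ± 0.24 (edgeR adjusted p = 0.0398, 0.0155, 0.00721 and 0.0274). DSE4 (2.07 ± 0.48) and the kinase gene RCK1 (1.41 ± 0.32) were higher too. The 1 ribosomal protein peak lower in Reductive Charging was shared by TOS6 and RPL18B (-1.92 ± 0.37, adjusted p = 0.0163). Also lower there were THI74 with GPI19 (-2.06 ± 0.41), CSI2 (-1.70 ± 0.39), CAF120, of the CCR4-NOT complex (-1.68 ± 0.33), and IDH2, isocitrate dehydrogenase (-1.58 ± 0.33, adjusted p = 0.0269). Histones were lower in Reductive Charging (2 of 6 peaks passed, those of HTA2 with HTB2 and of HHT2 with HHF2, and 2 adjusted over the list alone; camera adjusted p = 0.0201, and 0.387 with an estimated correlation). Histone scores were 0.48 and -0.003 at the Reductive Building time points 12 and 14, with Reductive Charging time point 17 (0.29) between them. In all 18 libraries the histone score difference was -0.62 (exact permutation adjusted p = 0.632).

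In all 18 libraries no peak passed this comparison (edgeR, 0 of 2086; 149 at an unadjusted p under 0.05; 20 with DESeq2, 0 with limma-voom), and no list passed. Stress promoters came nearest, 0.49 ± 0.32 (n = 8) against -0.41 ± 0.51 (n = 5) in score (exact permutation p = 0.00544, adjusted p = 0.0587; camera adjusted p = 0.0802). The poorly covered Reductive Building time points 11, 13 and 15 scored -0.69, -0.76 and -0.71. In the 13 well-covered libraries the stress difference was 0.33 (0.39 ± 0.16, n = 6, against 0.06 ± 0.57, n = 2; exact permutation p = 0.250, adjusted p = 0.4655; camera adjusted p = 0.529). RPL17B had 0.41 ± 0.70 and POX1 0.07 ± 0.99. The 13-library count of 30 was 14, 14, 3, 13 and 15 without time point 1, 2, 3, 4 and 5, 4 without 12, 137 without 14 and 50 without 17. With total-count scaling, which put the median of all peaks at -0.49, it was 15, all lower in Reductive Charging.

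By camera the remaining lists gave no call in all 18 libraries. Outside stress, trehalose and glycogen, and glyoxylate, 15 lists had camera adjusted p between 0.0517 and 0.954 over the 3 comparisons, the lowest for ribosome biogenesis (0.0517), then ribosomal proteins, amino acid biosynthesis, the mitochondrial ribosome and peroxisome and fatty acid oxidation (0.176 each). Mitosis and cytokinesis, glycolysis, proteasome, sulfur assimilation, histones, DNA replication, the respiratory chain, autophagy and vacuole, the subtelomeric PAU and COS families and RNA polymerase I and III followed (0.222 to 0.954). Among the genes taken from these lists, SHM2 had 2.77 ± 0.78 and LYS12 2.31 ± 0.80 in Oxidative against Reductive Charging (edgeR adjusted p = 1.00). The promoter of POX1, the fatty acyl-CoA oxidase chosen as a mark of Reductive Charging, had -0.83 ± 1.01 in the same comparison, and that of RPL17B, chosen as a mark of the Oxidative phase, had 0.50 ± 0.68, with no difference detectable at this spread. In lists without a call the median and the test could differ in sign, as for the proteasome (median -0.12 relative to all peaks, test up) in that comparison. No peak was linked to MRPL10. Of 54 list members named by rule, 0 passed in all 18 libraries and 9 did in the 13. The fold changes of 51 had the same sign in both, with STR3 (-1.96 ± 0.82 against 0.29 ± 0.24), HHO1 (-2.64 ± 1.22 against 0.25 ± 0.35) and ATP18 (-2.50 ± 1.01 against 0.74 ± 0.58) the exceptions. The 13 libraries are part of the 18, so the shared signs are no independent check.

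Peaks that differed among the 3 phases in any way were sought in 1 test. In all 18 libraries 0 of 2086 passed (edgeR; 113 at an unadjusted p under 0.05; 14 with DESeq2, 0 with limma-voom), and 58 did in the 13 well-covered ones. A smooth change over the ordered time points, fitted as a spline, gave 0 peaks in all 18 libraries (118 at an unadjusted p under 0.05; 53 with DESeq2, 5 with limma-voom) and 106 in the 13.

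Early (time points 1 to 5) and late (16 to 18) Reductive Charging carried the same label at the 2 ends of the series. Trehalose and glycogen promoters scored 0.36 ± 0.24 (n = 5) early and 1.25 ± 0.37 (n = 3) late, and glyoxylate promoters 0.13 ± 0.13 and 0.69 ± 0.33 (exact permutation p = 0.0179 and 0.0357; adjusted p = 0.0804 and 0.107 over 18 lists). Of 2085 peaks, 97 were higher early and 9 higher late (edgeR adjusted p under 0.05). The 5 highest, near NOP15, a ribosome biogenesis gene, RBL2, ICE2 with UTP25, HKR1 and HMT1, an arginine methyltransferase, had 0 counts in all 3 late libraries and early means of 26.9, 22.7, 22.3, 18.2 and 17.8 CPM. A count of 0 at time point 16 allows up to 0.0141% of that library's counts, more than these early means, so no lower bound on the fold follows for the 3 late libraries together. At the well-covered time point 17, 0 counts allow only up to 1.48e-05% (3 counts of the total), far below these early means. That floor takes every count as independent. Time point 17 had 42 nuclear peaks at 0, against 1.4e-18 expected from its depth, so the floor may be too low. The 5 peaks were also picked for the largest fold changes. Whether they were lower than early in that 1 library therefore stays open. Higher late were, most of all, STR3, of methionine metabolism (-3.75 ± 0.88, SE; edgeR adjusted p = 0.0285), the iron permease gene FTR1 (-3.38 ± 0.88, 0.0453), RRD1 (-3.38 ± 0.70, 0.0162), RIM8 (-3.29 ± 0.71, 0.0193) and SPS100 (-3.14 ± 0.77, 0.0342), as early minus late. At time point 17, the 1 well-covered late library, STR3 had 336 CPM against an early mean of 321 ± 48.6 (SD, n = 5), with 10075 CPM at time point 16 (389 counts) and 795 at 18. FTR1 had 0, 5.82 and 51.0 CPM at time points 16, 17 and 18, against 2.26 ± 1.52 early. RRD1, RIM8 and SPS100 had 148, 1194 and 40.7 CPM at time point 17, against early means of 18.0, 752 and 11.1. POX1 had 2.13 ± 0.96 (adjusted p = 0.252) and RPL17B 0.53 ± 0.64 (adjusted p = 0.755). Ribosome biogenesis had 5 of 31 peaks higher early (BUD22, NOP15, NUG1, SPB4 and UTP25) and amino acid biosynthesis 4 of 48 (HOM6, LYS9, LYS12 and TRP3). Ribosomal proteins had 3 of 120 (RPL23A, RPL35B and RPP1B) and the mitochondrial ribosome 3 of 25 (MRPL8, MRPL28 and RSM25). Of the stress, glyoxylate, and trehalose and glycogen peaks 0 passed (edgeR; 398 of the 2085 peaks had an unadjusted p under 0.05). Of the 97 peaks higher early, 96 had 0 counts at time point 16, as did 1720 of all 2042 nuclear peaks, and 56 had 0 counts at both 16 and 18, as did 260 of the 2042. The 106 calls were 62, 63, 70, 70 and 57 without time point 1, 2, 3, 4 and 5, and 296, 829 and 385 without 16, 17 and 18; loess offsets gave 313, of which 210 were higher late, a strict filter 1 and library weights 0.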

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

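The thinning test, the test of repeated counts and the tests of a single shift in time were chosen after the results were seen, as were the look for a batch, the test of 1 library deciding and the set of 13 libraries; the tests on matched lists and the splits of the libraries were written down before theirs.

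Several measures at time point 16, the library of 21254 counts, lay far from the other 7 Reductive Charging libraries: 84.2% of nuclear peaks at 0, and scores of -1.30 for ribosomal proteins, -1.15 for amino acid biosynthesis, 0.59 for the respiratory chain and ATP synthase, -1.05 for DNA replication and -0.93 for autophagy and vacuole, with a log2 CPM of -2.86 at the RPL17B peak, where it had 0 counts. Time point 18 stood apart for mitosis and cytokinesis (-2.08) and stress (1.22). Time point 8 stood apart from the other Oxidative libraries for autophagy and vacuole (0.20). Among Reductive Building libraries, time point 13 stood apart for glycolysis (1.66) and time point 15 for the RPL17B peak (-2.86, 0 counts). Of 69 groups examined 12 held such a library, against 3.45 expected by chance at 1 in 20.

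The first pattern is the 5 libraries with more than 10% of nuclear peaks at 0. Fewer counts alone is argued against: all 5 had more peaks at 0 than every well-covered library thinned to the same nuclear count (at time point 11, 229 against 0 to 57). Few independent fragments, each counted many times, stays open: in 4 of the 5 libraries peaks expected to hold under 0.5 fragments had a median count above 10 where not at 0, but depth alone already expects that in 4, so the test decides nothing. Of the 5, 3 are Reductive Building libraries, so a difference in chromatin or in nuclei between phases stays open and was not tested.

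The second pattern is the lower accessibility of stress, trehalose and glycogen, and glyoxylate promoters in Oxidative libraries. Peak strength or length is argued against as the whole cause, since the differences of all 3 lists lay below the 2.5th percentile of 10000 lists matched on both (percentiles 0, 0 and 0.05), though lists matched to glyoxylate had a median of -0.24 and a 2.5th percentile of -0.58, against its -0.80. A single lasting shift after time point 7 is argued against for stress and glyoxylate, since their mean scores at time points 12, 14 and 17 (0.269 and 0.536) were above the highest at 8 to 10 (-0.67 and -0.56), and both 6 and 7 (-0.01 and -0.08 for stress, -0.06 and -0.26 for glyoxylate) were below the lowest at 1 to 5 (0.25 and -0.01); stress at time point 12 alone was -0.35, and at the poorly covered 11, 13 and 15 (-0.69, -0.76 and -0.71) in the range of 8 to 10. Glyoxylate at time point 6 was below 1 to 5 by less than their SD (0.13). For trehalose and glycogen the test as written was undecided, since time point 6 (0.11) lay in the range of 1 to 5 (lowest 0.08). Its scores of -0.50, 0.68 and 0.83 at time points 12, 14 and 17 (mean 0.337) were above the highest at 8 to 10 (-0.70). These scores argue against a shift that lasted. Time point 12 was the nearest to 8 to 10, and the poorly covered 11 (-0.70) lay in their range. An unrecorded batch cannot be told apart from the phases, since the labels give the batch of 0 libraries, and a link to the metabolic phase stays a hypothesis.

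The third pattern is the lower accessibility of ribosomal protein promoters in Reductive Building than in Oxidative libraries among the 13 well-covered. Peak strength or length is argued against (percentile 0 of matched lists; -0.58 against a 2.5th percentile of -0.19). The direction did not rest on 1 Reductive Building library: the difference was -0.77 without time point 12 and -0.40 without time point 14. The smaller was 0.684 of that with both. No Oxidative library was left out in that test, so whether 1 of those decides the difference was not tested. Scores of 0.53 and 0.73 at time points 11 and 13 go the other way, and whether they come from poor coverage was not tested, so a place within the phase and the state of the libraries both stay open.

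Regrouping the libraries tested whether chance could give as many calls. With all 18 libraries chance cannot be excluded: all 100 splits gave at least the 0 peaks observed for differences among phases, for each of the 3 phase comparisons and for time (highest of the other splits 8, 2, 11, 14 and 6), and 21 of 100 gave at least the 3 list and comparison pairs observed (highest 9); estimated correlations within lists were 0.37 to 0.65, against the preset 0.01, and whether these or another structure of the samples gave such splits was not tested. As the observed 0 is met by any split, the counts of peaks test nothing there. For early against late Reductive Charging, 1 of 56 splits, the real one, gave 106 peaks, and the highest of the others was 0. Among the 11 well-covered Oxidative and Reductive Charging libraries, 1 of 100 splits gave 58 peaks (highest other 1). Chance would be excluded for these 2 counts of peaks only if libraries could be exchanged freely, and neighbouring time points are not independent. The 8 Reductive Charging libraries also differ in coverage: time points 16 and 18 had 1720 and 266 nuclear peaks at 0. For early against late, 1 of 56 is the smallest share possible. The 58 peaks come from a set chosen after seeing the data and were 4 to 12 without any 1 of 8 libraries. Chance is therefore not taken as excluded for either count. An unrecorded batch at the ends of the series cannot be told apart from early and late. In the same 11 libraries 4 of 100 splits gave at least the 6 lists observed and the highest other gave 8, and chance is not taken as excluded for the lists either.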

How the results depend on the processing

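Chosen after seeing the data were the fits without poorly covered libraries, nuclear peaks only, library weights, the score tests with their alternatives, the shares of mitochondrial counts, and every setting of the 13-library counts; the cause of each change was not tested. Depth limits single peaks most at time point 16, where 0 counts allow a share of up to 0.0141%. With all 18 libraries, Oxidative against Reductive Charging kept 0 peaks in every setting fixed beforehand except the fit of only those groups (1 peak). Values that stayed on their side are not listed.

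With loess offsets 309 peaks were called for Reductive Building against Oxidative, 549 for Reductive Charging against Reductive Building, 526 among the 3 phases, 597 over time and 313 for early against late Reductive Charging, where the direction of most calls turned (103 higher early, 210 lower). DESeq2 gave 13, 20, 14, 53 and 353 in the same order. limma-voom gave 3 for Reductive Building against Oxidative and 5 over time. A strict filter gave 1 for Reductive Building against Oxidative and 1 for early against late, with fewer peaks tested. DESeq2 size factors gave 171 for early against late. With Reductive Charging time points 1 to 5 only, Reductive Building against Oxidative had 2 peaks and the 3 phases 1, and with time points 16 to 18 only the 3 phases had 2. Without the first and last time point of each phase, Reductive Building against Oxidative had 7.

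Without the 5 poorly covered libraries the counts were 58 for Oxidative against Reductive Charging, 31 for Reductive Building against Oxidative, 30 for Reductive Charging against Reductive Building, 58 among the phases and 106 over time. Without the 2 libraries with more than 50% of nuclear peaks at 0 they were 5 for Reductive Building against Oxidative, 2 for Reductive Charging against Reductive Building, 2 among the phases, 105 over time and 296 for early against late. Library quality weights (limma-voom) gave 100 for Oxidative against Reductive Charging, 118 among the phases, 222 over time and 0 for early against late. Past the same adjusted threshold, edgeR gave 106 and DESeq2 353 for early against late. At an unadjusted p under 0.05 that comparison had 226 peaks with weights and 398 by edgeR.

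Among the 13 libraries, total-count scaling gave 114, 0 and 15 peaks for Oxidative against Reductive Charging, Reductive Building against Oxidative and Reductive Charging against Reductive Building (for the 0, edgeR; 178 at an unadjusted p under 0.05), of which 35, 0 and 12 were among the 58, 31 and 30. DESeq2 gave 131, 114 and 59, which held all 58, 31 and 30, and limma-voom gave 58, 61 and 19, of which 40, 30 and 17 were among them. List and comparison pairs past the threshold were 3, against 0 with an estimated correlation (camera; 1 at an unadjusted p under 0.05), 12 in the 13 libraries and 13 without the 2 emptiest. Stress, trehalose and glycogen, and glyoxylate were each called in 24 of 25 settings for Oxidative against Reductive Charging. The exception among the 25 was the estimated correlation in all 18 libraries. Of the 25 settings, 18 left out 1 library each and kept the preset correlation. Tests outside the 25 also lost these calls. Fry in all 18 libraries gave adjusted p = 0.983, 0.942 and 0.942. Camera with an estimated correlation in the 13 libraries gave adjusted p = 0.191, 0.239 and 0.193. Fry in the 13 libraries called all 3 (adjusted p = 0.0154, 0.0222 and 0.0143). The score test in the 13 libraries, not among the 25, gave differences of -0.88, -0.995 and -0.72 and called none (adjusted p = 0.0584 each), although stress and glyoxylate were at the smallest exact p possible (0.00216). Within time points 1 to 7 the trehalose and glycogen score differed by -0.42 (exact p = 0.143). The mitochondrial share differed by -24.2 points in the 13 libraries and by -14.5 within time points 1 to 7 (exact p = 0.0476).

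Leaving out 1 library at a time gave 0 to 0 peaks for Oxidative against Reductive Charging, 0 to 36 for Reductive Building against Oxidative, 0 to 37 for Reductive Charging against Reductive Building and 0 to 18 among the phases, each highest without time point 14. It gave 0 to 8 over time (highest without time point 15) and 57 to 829 for early against late (lowest without 5, highest without 17). In the 13 libraries it gave 4 to 119, 14 to 104 and 3 to 137 for the phase comparisons in the order above. List pairs were 3 to 8, highest without time point 16. Score differences were -1.11 to -0.88 for stress, -1.42 to -1.13 for trehalose and glycogen and -0.90 to -0.72 for glyoxylate, and the mitochondrial share -19.9 to -12.1 points, past the threshold without time point 16. Named genes in all 18 libraries gave 2004 values that stayed as in the report. Those passed the threshold in both settings with the same sign, or passed in neither and moved by less than their SE. In the latter case the sign could differ. A further 140 moved by more than their SE, 46 were weaker and 40 stronger. Genes named in the 13 libraries gave 310 values that stayed and 200 that no longer passed, with 0 reversed.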

Other observations

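All tests in this part were chosen after the results were seen. Transfer RNA genes lay within 100 bp of 215 nuclear peaks. Accessibility of RNA polymerase I and III subunit promoters was 0.09 ± 0.42 (score, SD, n = 5) in early and -0.92 ± 0.36 (n = 3) in late Reductive Charging, that of mitochondrial ribosome promoters 0.00 ± 0.11 and -0.54 ± 0.16, and that of amino acid biosynthesis promoters -0.08 ± 0.09 and -0.63 ± 0.46 (two-sided exact permutation p = 0.0179 each, the smallest possible; adjusted p = 0.0804 over 18 lists). At time point 17, the single well-covered late library, the 3 scores were -0.51, -0.41 and -0.28. Peroxisome and fatty acid oxidation promoters scored -0.24 ± 0.23 (n = 5) in Oxidative and 0.17 ± 0.14 (n = 6) in Reductive Charging libraries among the 13 well-covered (exact permutation p = 0.00433, adjusted p = 0.0584). In all 18 libraries their difference was -0.41 (exact permutation p = 0.0723, adjusted p = 0.300).

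Time points 6 and 7, the first of the Oxidative phase, had stress scores of -0.01 and -0.08, between those of time points 1 to 5 and of 8 to 10. Within time points 1 to 7, which resembled each other most, the 2 Oxidative libraries lay below all 5 Reductive Charging libraries for stress (-0.37) and glyoxylate (-0.30), and above them for sulfur assimilation and methionine (0.17); the exact permutation p was 0.0476 for each, the smallest that 2 against 5 can give (adjusted p = 0.286).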
